A study of Caenorhabditis elegans with 4 samples.

How the data were processed

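Binding of the transcription factor ZTF-4 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hermaphrodite larvae of Caenorhabditis elegans at the L2 stage. Per the labels' protocols, worms of a strain carrying a tagged ztf-4 transgene together with an unc-119 rescue were grown at 20 degrees Celsius and fixed with 2% formaldehyde. Chromatin was sheared by sonication and the tagged protein was pulled down with a goat antibody against GFP. Part of each lysate was kept as input DNA. The series holds 4 samples, 2 ChIP and 2 input, and the groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate worm cultures, so the spread between them may be technical, and p-values measure only the placement or strength of sites within these lists. Values per input sample were not analysed here.

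The values analysed were the start, the end and the q-value of each binding site. The authors deposited a list of sites for ChIP replicate 1, another for ChIP replicate 2 and a combined list for the series. Sites were called with PeakSeq on WormBase release WS180, per the file headers and the source field of each line. The q-value of each site is the authors' own, and the score field repeated it exactly in every line of the 3 lists. PeakSeq's version, the aligner, the read filters, the matching of ChIP to input and the way the replicates were combined are not given in the sources used here. The lists hold no read counts, fold enrichments or summits, so the read depth of each sample is unknown and the strength of a site is known only through its q-value. A q-value depends on depth as well as on enrichment, so a difference in q between lists is not a difference in occupancy. The highest q listed was 9.41e-05 in replicate 1, 9.22e-05 in replicate 2 and 0.00015 in the combined list, so the lists hold only sites past a limit, and a site missing from a list is not shown to be unbound.

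Lists were compared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A site counted as shared when it overlapped a site of the other list by at least 1 bp. The chance level came from moving all sites of one list by a random circular offset within each chromosome, 100000 times, which keeps their widths and spacing. The p-values of these permutation tests are one-sided, and the smallest they can give is 1e-05. Strength was compared across regions called in both replicates, with the strongest site of each replicate per region, by Spearman and Pearson correlation of −log10 q with two-sided permutation p-values from 100000 resamples. These correlations run across sites, which are not independent replicates. The number of sites per chromosome was tested against chromosome length with two-sided exact binomial tests, adjusted by Benjamini-Hochberg over the 6 chromosomes. WS180 chromosome lengths were not available to the analysis, so the highest site end in any list stood for the length. The centre of a chromosome was its middle part, from 25 to 75% of that length. Intervals of shares are 95% Wilson intervals. They and the binomial tests treat sites as independent, cover counting error only, and are therefore too narrow where sites lie in groups.

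Loci for the comparison of replicate and combined strength were chains of replicate sites less than 500 bp apart. The combined −log10 q was fitted by a straight line to the sum of the replicates' −log10 q over the 44 loci with a sum of at least 60, with all sites of a locus added up and with 95% prediction intervals. Spacing was tested by placing every site at random in its own 1 Mb bin, 10000 times, with a one-sided p whose smallest value is 0.0001. The share of chromosome I was compared between support classes within 10 groups of like combined q by a Mantel-Haenszel odds ratio, with a two-sided permutation p from 100000 draws within the groups.

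The shift and binomial tests were first tested on simulated lists. Over 100 pairs of unrelated lists drawn at the sizes of the replicate lists, 2.0% gave a shift p under 0.05. The shifted list started from 813 sites, and simulated sites that overlapped an earlier one were dropped. The overlap call matched a direct search at 100.0% of 1167 sites. With 1828 sites, the binomial test called a 50% deficit on X in 100.0% of 100 runs and called X in 5.0% of 100 runs without a difference. The simulated sites were placed independently of each other, while the real sites lie in groups. These rates therefore need not hold for the real lists.

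The main tests, most of their alternatives and the rule for naming sites were fixed before the data were examined. Chosen later were the alternatives of q limits other than 0.001, local shifts, width in place of q, weaker regions alone, nearby sites counted once and absent loci added, and also the spacing test, the tests of 1 Mb bins, the difference between the autosomes and X, the grouping of sites by q, the comparison of loci between replicate and combined lists, the tests across support classes and the comparison of chromosome ends. The rule named the 20 strongest combined sites, by q, that overlapped a site in both replicate lists. Alternatives were other definitions of overlap, each replicate list alone, sites found in both replicates, the stronger and weaker part of the combined list, other q limits, nearby sites counted once and the absent loci added. The plan also held 6 results that need the sequence or gene annotation of WS180: the share of sites at promoters, the distance to gene starts, GC content, enriched 6-mers, the tests of 22 gene lists and 5 RNA classes, and the sites at the loci carried by the transgene. The gene table at hand is of the WBcel235 assembly, so its coordinates were not set against WS180 sites. These results were not analysed here, and sites are given by position, without gene or exon annotation.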

Results

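The data describe where ZTF-4, a transcription factor fused to green fluorescent protein (GFP), bound the genome of Caenorhabditis elegans in whole L2 larvae. The 2 ChIP samples gave 744 binding sites in replicate 1 and 813 in replicate 2, and the combined list held 1828. The sites of replicate 1 covered 747790 bp, those of replicate 2 covered 863750 bp and the combined sites covered 1729887 bp, or 1.73% of the span of the 6 chromosomes. The median site was 702 bp wide in replicate 1, 732 bp in replicate 2 and 636.5 bp in the combined list. The widest reached 13138 bp, 15814 bp and 7493 bp in the same order. At a common limit of q under 1e-05, 546, 587 and 1305 sites remained. All positions below are on WormBase WS180 and 1-based, and the q-values are the authors'.

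The first comparison asked whether both ChIP samples marked the same places. Of the replicate 1 sites, 588 (79.0%, 95% interval 76.0 to 81.8%) overlapped a replicate 2 site. Of the replicate 2 sites, 581 (71.5%, 68.3 to 74.5%) overlapped a replicate 1 site. Shifted lists overlapped at 1.67% and 1.52% on average, and none of 100000 shifts reached the observed value (permutation p = 1e-05 for both, the smallest the test can give). The union of both lists formed 946 regions, of which 558 (59.0%) were called in both. With midpoints within 100 bp required in place of 1 bp of overlap, the shared part was 46.0% of replicate 1 and 42.1% of replicate 2 (permutation p = 1e-05 for both). In the 558 regions the midpoints of the paired sites lay a median of 71.5 bp apart.

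Overlap followed the strength of the site. Each list was divided by q into 4 groups of like size. Of the 186 replicate 1 sites with the lowest q, all had a partner in replicate 2, and of the 186 with the highest q, 97 did (52.2%, 45 to 59%). In replicate 2 the partners numbered 203 of 204 sites and 80 of 203 sites (39.4%, 33 to 46%). Sites without a partner had a median −log10 q of 4.79 in replicate 1 and 4.83 in replicate 2, against 7.47 and 8.07 for sites with one. They were also narrower, with median widths of 491.5 against 789.5 bp in replicate 1 and 575.5 against 844 bp in replicate 2. A wider site meets the 1 bp rule more easily, and strength was not separated from width. Across the 558 shared regions the −log10 q of both replicates rose together, with a Spearman rho of 0.816 and a Pearson r of 0.984 (permutation p = 1e-05 for each, across sites). Without the 2 regions farthest from the median, r was 0.976 and rho 0.814. Without the strongest regions by replicate 1, over the 418 regions left, r was 0.601 and rho 0.604. Of the 20 strongest sites of each replicate, 17 regions were common to both.

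**Figure D1:**
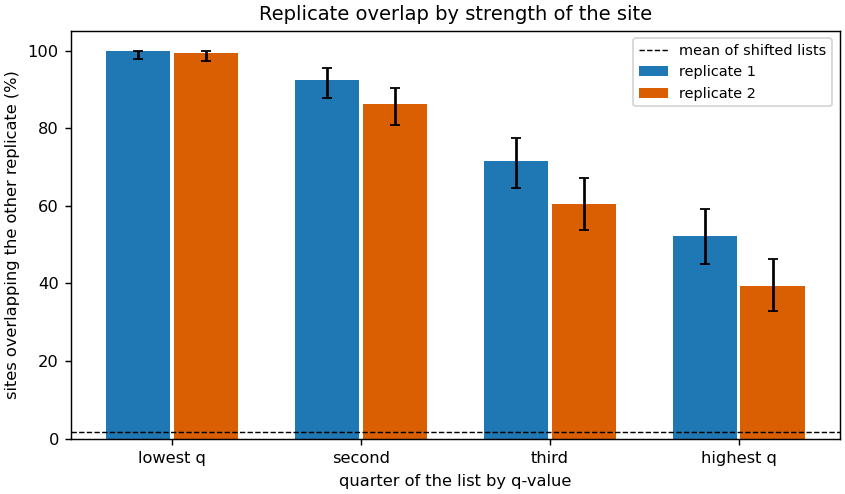
Percentage of sites (y axis) that overlapped a site of the other replicate, for 4 groups of each replicate list ordered by q-value (x axis). Bars are replicate 1 and replicate 2, and error bars are 95% Wilson intervals. The dashed line is the mean of shifted lists over all replicate 1 sites, 1.67%, not over each group. For all replicate 2 sites that mean was 1.52%. The percentage fell from 100% and 99.5% in the strongest group to 52.2% and 39.4% in the weakest.

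**Figure D2:**
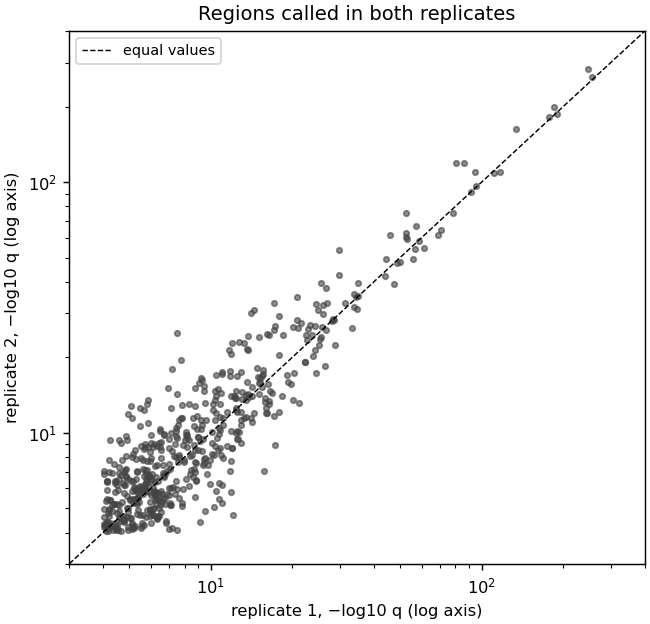
−log10 q in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, for the 558 regions called in both; each point is a region and the dashed line marks equal values. The points rise along the line, with a Spearman rho of 0.816.

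The second comparison set the combined list against the replicates. Of the 1828 combined sites, 527 (28.8%, 26.8 to 30.9%) overlapped a site in both replicate lists, 343 (18.8%) in 1 of them and 958 (52.4%, 50.1 to 54.7%) in neither. With midpoints within 100 bp required, 12.7% were found in both. Shifts of the combined list gave an overlap of at least 1 bp with both replicates at 1.16% of sites (permutation p = 1e-05). By its name the combined list draws on the same ChIP samples, so an excess over shifts is not independent evidence of agreement. Sites found in both replicates were stronger and wider, with a median −log10 q of 16.5 and a median width of 1107 bp, than sites found in neither, with 4.97 and 498.5 bp. The combined list held 716 of the 744 replicate 1 sites (96.2%) and 795 of the 813 replicate 2 sites (97.8%).

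The 20 strongest combined sites found in both replicates were also ranks 1 to 20 of the whole combined list. Chromosome II held 7 of them, I held 4, IV held 3, and III, V and X held 2 each. The strongest was on I, from 7656151 to 7661472, with q = 9.24e-228 in the combined list, 5.82e-87 in replicate 1 and 1.92e-120 in replicate 2. Next were IV from 3644567 to 3648312 (q = 2.94e-215), II from 8742969 to 8748098 (2.58e-210), III from 9050385 to 9055104 (6.01e-187) and III from 8443223 to 8447425 (2.24e-181). The strongest site on X ran from 12662175 to 12669445 (q = 2.43e-156), and the strongest on V, from 13652186 to 13659678 (q = 1.31e-134), was the widest of the combined list. Of the 20 sites, 17 were wider than 3000 bp. The narrowest were both on II, from 11756207 to 11757174 and from 11761606 to 11762663, with q = 5.31e-117 and 1.03e-133. Among the remaining 11 were sites on X at 6251995 to 6257533, on I at 8865319 to 8868864, on V at 723424 to 729899, on IV at 17276819 to 17281833 and on II at 8477904 to 8482570. Every one of the 20 ranked 41 or better in replicate 1 and 39 or better in replicate 2.

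The strongest replicate sites were missing from the combined list. Only 3 of the 10 strongest sites of replicate 1 and 4 of the 10 strongest of replicate 2 overlapped a combined site, while all 10 of replicate 1 overlapped replicate 2. Of 528 loci called in both replicates, 520 had a combined site and 8 had none. These 8 were II from 10541755 to 10557606, X from 4137557 to 4149328, I from 7078758 to 7086257, X from 16929251 to 16932037, V from 6220684 to 6230398, I from 5372099 to 5380221, II from 14598154 to 14609384 and I from 15063996 to 15067644. The first had q = 5.63e-249 in replicate 1 and 4.26e-283 in replicate 2, and the last 5.65e-112 and 2.66e-109. The loci that hold ranks 1 to 6 of both replicate lists are among these 8, so the 20 strongest combined sites leave them out. In 44 strong loci with a combined site, the combined −log10 q was 0.97 ± 0.0404 (SE) times the sum of the replicates' values, plus 2.62 (r = 0.965, across loci).

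**Figure D3:**
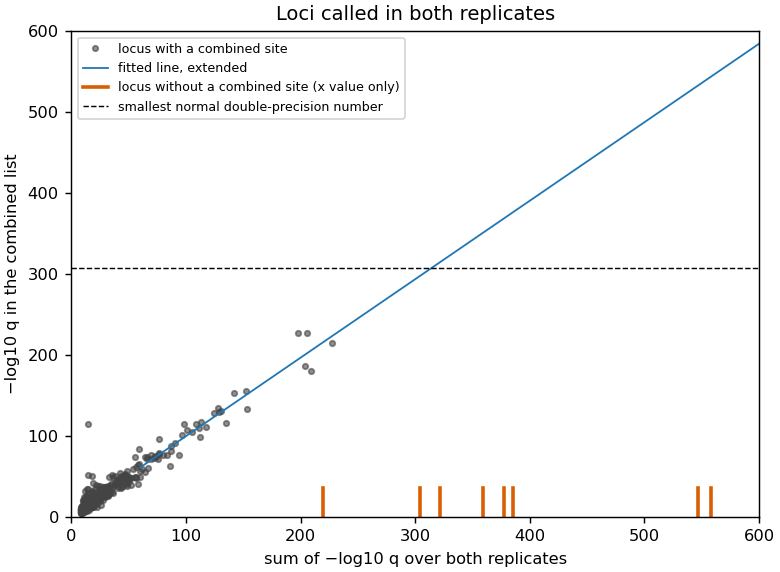
Sum of −log10 q over the sites of both replicates (x axis) and over the combined sites (y axis) for loci called in both replicates; points are the 520 loci with a combined site, which may span several loci, orange ticks mark the x values of the 8 loci without one, the blue line is the fit over 44 loci, extended, and the dashed line is the −log10 of the smallest normal double-precision number, 308. The points end at a sum of 227, and 7 of the 8 ticks lie beyond 300.

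The third comparison was between chromosomes. Chromosome III carried more sites than its length predicts and chromosomes V and X carried fewer, in the combined list and in each replicate list. In the combined list III held 20.5% of sites (18.7 to 22.4%) against 13.8% expected, or 27.2 sites per Mb (exact binomial test, adjusted p = 2.56e-14). V held 14.1% against 20.8% expected (12.3 per Mb, exact binomial adjusted p = 2.75e-13) and X held 12.7% against 17.6% (13.2 per Mb, adjusted p = 2.12e-08). In replicate 1 and replicate 2 the shares were 22.7% and 21.6% on III, 15.5% and 15% on V, and 14.2% and 14.1% on X, with the highest exact binomial adjusted p at 0.032, for X in replicate 1. Chromosome I held 19.5% of combined sites against 15.1% expected (exact binomial adjusted p = 4.05e-07), but 13.3% of replicate 1 and 15.4% of replicate 2 sites (adjusted p = 0.296 and 0.806). The combined shares of II (12.9% against 15.2%, exact binomial adjusted p = 0.00563) and IV (20.4% against 17.5%, adjusted p = 0.0018) also passed the test only in the combined list among these 3 lists. When sites within 20 kb of each other were counted once, V still passed (16.7%, exact binomial adjusted p = 0.0145), and III (16.5%, adjusted p = 0.0639) and X (15.8%, adjusted p = 0.17) did not. X also missed the threshold among sites found in both replicates (15.2%, exact binomial adjusted p = 0.306).

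**Figure D4:**
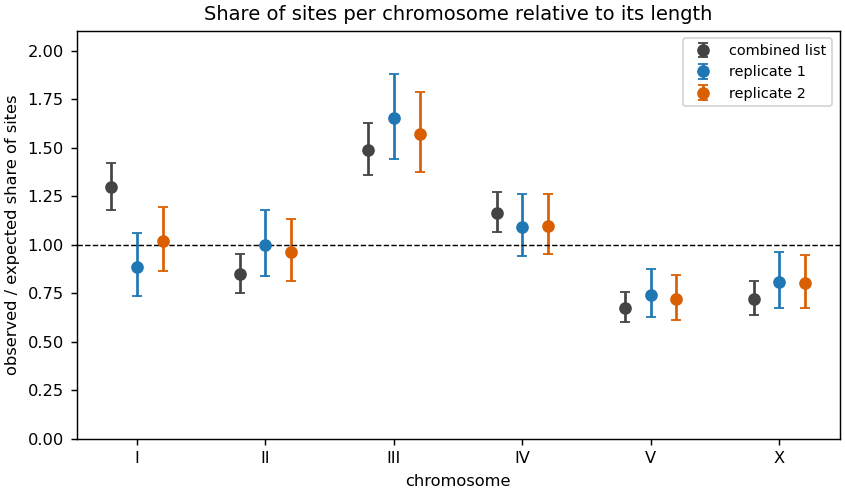
Observed over expected share of sites (y axis) for each chromosome (x axis), where the expected share is the chromosome's part of the total length; points are the combined list and both replicate lists, error bars are 95% Wilson intervals and the dashed line is a ratio of 1. III lies above 1 and V and X below 1 in all 3 lists (1.49, 0.675 and 0.720 in the combined list), while I is at 1.30 in the combined list, 0.883 in replicate 1 and 1.02 in replicate 2.

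Within the autosomes, sites were concentrated in the chromosome centres. The centre held 1004 of 1596 autosomal combined sites (62.9%, 60.5 to 65.2%, exact binomial test against 50%, p = 4.38e-25), which is 24.4 sites per Mb against 14.4 in the outer parts. The replicate lists gave 63.2% and 65.5%. Each autosome passed the test in the combined list, from 57.8% on IV (exact binomial adjusted p = 0.00368) to 70.0% on V (adjusted p = 6.78e-10). In replicate 1, I and IV did not pass (56.6% and 53.5%, exact binomial adjusted p = 0.342 and 0.45). With sites within 20 kb counted once, I (55.2%, exact binomial adjusted p = 0.272), III (58.6%, 0.0909) and IV (57.3%, 0.0909) did not pass, while II and V did. On X the centre held 108 of 232 sites (46.6%, 40.2 to 53.0%, exact binomial adjusted p = 0.325), with 12.3 sites per Mb in the centre and 14.1 outside. The difference between the autosomes and X was itself past the threshold, with an odds ratio of 1.95 in the combined list (Fisher's exact test, two-sided, p = 2.6e-06), 2.07 in replicate 1 (p = 0.00058) and 2.47 in replicate 2 (p = 1.06e-05).

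By 1 Mb bins, the densest stretch was III from 5000001 to 6000000, with 54 combined sites, 22 in replicate 1 and 23 in replicate 2, the highest count in each list. It was followed in the combined list by I from 7000001 to 8000000 with 43 sites and I from 9000001 to 10000000 with 41. The median full bin held 17 combined sites, and the lowest, II from 1000001 to 2000000, held 1. Over the 97 full bins the counts of both replicates correlated with a Pearson r of 0.902 and a Spearman rho of 0.889 (permutation p = 1e-05 for each, across bins).

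**Figure D5:**
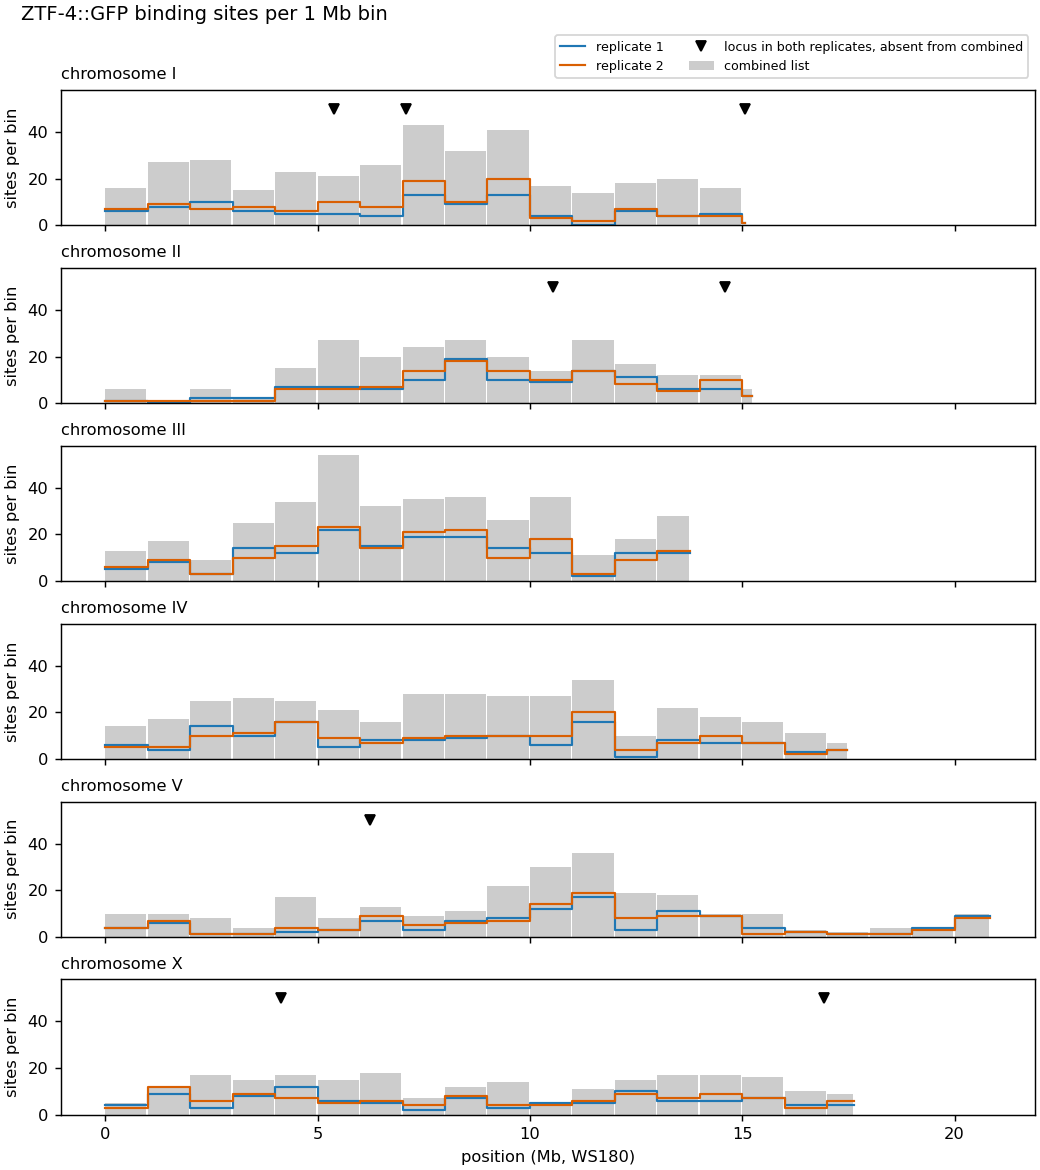
Number of sites per 1 Mb bin (y axis) along each chromosome (x axis, position in Mb on WS180); grey bars are the combined list, lines are both replicate lists and triangles mark the 8 loci called in both replicates and absent from the combined list. The highest bar is the bin on III with 54 sites, and the lowest full bin, on II, has 1.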

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

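The alternatives of q limits other than 0.001, shifts of 20 to 500 kb, width in place of q, weaker regions alone, nearby sites counted once and absent loci added were chosen after the data were seen, as was every test of spacing and of the autosome-to-X difference. Of 77 alternative values over the 13 results with a test, 60 kept their direction and their side of the threshold. These included every alternative run for the overlap of the replicates, the correlation of site strength, the sites found in both replicates, the centres of the 5 autosomes as a whole, the autosome-to-X difference and the spacing. The test of combined sites found in both replicates compares lists of the same samples, so its result is not independent evidence. Adding the absent loci puts 8 loci beside 1828 combined sites, so that alternative could move a share only slightly. Of the autosomes singly, II and V passed in every alternative, III in all but nearby sites counted once, and I and IV missed the threshold in several, down to 53.5% for IV in replicate 1. Under the strictest overlap, midpoints within 100 bp, the shared parts of 46.0% of replicate 1, 42.1% of replicate 2 and 12.7% of the combined list stood against shifted means of 0.174%, 0.16% and 0.0658%. A limit of q under 0.001 removed no site, and q under 1e-10 left 537 combined, 212 replicate 1 and 226 replicate 2 sites. The shares of chromosomes depended on the list and on whether nearby sites were counted once. Over the single replicate lists the share was 13.3 to 15.4% on I, 14.6 to 15.2% on II and 19.1 to 19.2% on IV. In sites found in both replicates it was 13.5% on I, 15.6% on II, 18.4% on IV and 15.2% on X, so that I and II changed sides of their expected 15.1% and 15.2%, I also in replicate 1. The stronger part of the combined list gave 14.2% on II and 19.8% on IV, neither past the threshold. With sites within 20 kb counted once, which leaves 879 groups, the shares were 17.5% on I, 13.2% on II, 16.5% on III, 20.3% on IV and 15.8% on X, none past the threshold. These alternatives hold fewer sites than the combined list. For I, explanations of the difference between sites found in neither and in both replicates are weighed below. The cause of the other changes was not tested. V passed in every list and alternative run. No paired analysis was possible because values per input sample were not analysed here and the tests compare lists of sites. The planned expectation from gene numbers, a further numeric field for ranking and all alternatives of the promoter, sequence and gene list results were not run, for want of a WS180 annotation or of such a field. Read depth is unknown, so sites near the q limit that occur in 1 list cannot be called absent from the other sample.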

Other observations

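The tests of spacing, chromosome ends and the first 2 patterns in this part were chosen after their results were seen. Those of chromosome I were chosen after the pattern but before their own results. The shares of I in the stronger and weaker parts of the combined list were an exception, chosen before the data were examined. Sites lay close together more often than chance. In the combined list 40.1% of sites had a neighbour within 2 kb, against 12.3% when sites were placed at random within their own 1 Mb bin (permutation p = 0.0001, the smallest possible), and the replicate lists gave 35.6% and 35.9% against 5.42% and 6.09%. PeakSeq can split a broad region into adjacent sites, and no signal track was used to tell such pieces from separate sites. The largest group with gaps under 20 kb was on I from 9076022 to 9136055, with 11 combined sites, of which the region held 4 in replicate 1 and 5 in replicate 2. On III from 3771120 to 3812985 there were 10 combined sites, 6 in replicate 1 and 5 in replicate 2. Groups of 9 combined sites lay on II from 11723948 to 11762663, with 7 in each replicate, and on IV from 3106726 to 3135453, with 4 in replicate 1 and 2 in replicate 2.

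Chromosome II was lopsided. The first 25% of its length, up to position 3807770, held 13 combined sites and the last 25%, from 11423311, held 70 (exact binomial test, adjusted p = 7.98e-10 over 6 chromosomes). Replicate 1 gave 3 and 38 and replicate 2 gave 3 and 39. With sites within 20 kb counted once the counts were 9 and 29 (exact binomial p = 0.00166). III leaned the same way, with 42 and 84 combined sites (exact binomial adjusted p = 0.00069), but 25 and 35 once grouped (p = 0.245). V leaned to the left in the combined list with 50 and 27 (exact binomial adjusted p = 0.0234), but replicate 1 gave 15 and 19 (p = 0.608), replicate 2 gave 18 and 15 (p = 0.728), and grouped sites gave 31 and 19 (p = 0.119). Of the 29 combined sites under 100 bp wide, 28 were found in neither replicate list, and the narrowest was 2 bp.

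The 8 loci that both replicates called and the combined list lacks form the first pattern, and 2 candidate explanations are that q-values too small for a double-precision number were dropped and that sites above a width limit were dropped. For the number limit, 0 loci with a summed −log10 q over 300 are present. With the strongest site of each replicate alone, 5 absent loci pass 300. The sums of present loci end at 227, so any cut from there to 300 gives 0. The count therefore restates the pattern and does not decide. Lower 95% prediction limits of the combined value for the 5 loci run from 319 to 500, above the number limit of 308. They rest on the fitted line extended past 227, where no present locus can test it, so they do not decide either. I from 5372099 and II from 14598154 pass 300 only with several sites added, their strongest sites summing to 297 and 183. Their 95% prediction intervals, 285 to 345 and 269 to 326 with all sites added, include 308, and both loci stay open. The upper 95% prediction limit of 241 for I from 15063996 stays under the limit of 308 and argues against the number limit there. For the width limit, 3 loci have a single replicate site wider than the widest combined site of 7493 bp. These are II from 10541755, X from 4137557 and V from 6220684. All are among the 5 above, so the 2 explanations cannot be told apart there. Another 3 reach that width only when overlapping or nearby replicate sites are joined (widest single site 7443 bp) and stay open. For I from 7078758 the joined sites are 1 from each replicate, which overlap and together span 7500 bp. The locus on X from 16929251 would need a combined site 2.69 times as wide as its replicate sites, beyond the highest ratio of 2.12 among 44 strong loci, which argues against a width limit there; I from 15063996 would need 2.05, reached by 1 of the 44, and neither removal of listed regions nor a biological explanation was tested.

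The second pattern is that 52.4% of the combined sites lie in neither replicate list. A candidate explanation is that sites that narrowly miss the limit in each replicate pass it when evidence is pooled. The lowest −log10 q in a replicate list was 4.03, and 92.3% of these sites had a combined value at or under 8.05, which is 2 times that limit, but absence from both lists by itself favours low combined values, so this share does not decide and pooling stays open. The remaining 74 sites lie above that value, the strongest being IV from 15271902 to 15274453 (q = 5.37e-21). A value of 8.05 is no upper bound on pooling, since combined values of weak shared loci departed from their sums both ways (IV from 4049549, sum 8.54 and combined 11.9, and III from 10090350, sum 8.77 and combined 4.31). How the authors combined the replicates is not given in the sources used here, and no biological explanation was tested.

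The third pattern is that chromosome I held 23.7% of the combined sites found in neither replicate but 13.5% of those found in both (odds ratio 1.99, Fisher's exact test, adjusted p = 1.16e-05 over 6 chromosomes; no other chromosome passed). A few dense groups of sites on I may account for part of this. With sites within 20 kb counted once in each class, the odds ratio fell to 1.57 but stayed above 1 (Fisher's exact p = 0.0134, not adjusted over chromosomes). That left 636 groups found in neither, 20.0% of them on I, and 379 found in both, 13.7% on I. A stretch with sites of both classes can count in both. That weak sites lie on I more often in the combined list is argued against: within 10 groups of like combined q the odds ratio was 6.54 (permutation p = 1e-05, the smallest possible), and the stronger and weaker parts of the combined list held 19.3% and 19.8% on I. Only 8 of these groups held both classes, and the weaker groups held few sites found in both. The odds ratio therefore does not cover all strengths evenly. The replicate lists decide nothing, since they went opposite ways: the weaker part minus the stronger averaged 0.416 percentage points, with 12.6% against 14% in replicate 1 (Fisher's exact p = 0.666) and 16.5% against 14.3% in replicate 2 (p = 0.437). A property of the combined calling on I, such as the input used, was not tested, and the design gives no group that would offer a biological explanation.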
